A study of Mus musculus with 15 samples.

How the data were processed

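RNA was sequenced from whole lungs of 15 female Balb mice in 3 groups of 5. Per the labels, 5 animals were sham-sensitised with saline and given an isotype control antibody, 5 were sensitised and challenged with ovalbumin (OVA) and given the isotype control, and 5 were sensitised and challenged with OVA and given a monoclonal antibody against mouse IL-4Ra at 30 mg/kg. Per the labels' protocols, lungs were snap frozen and homogenised, RNA was extracted with Trizol and columns, and strand-specific libraries were made with dUTP. The protocols name both a depletion of ribosomal RNA and a purification with oligo-dT beads, so it is open which of them set the RNA classes that were sequenced. Sequencing dates, batches and the timing of doses and tissue collection are not given in the sources used here.

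The values are expected counts per gene symbol, 1 column per animal, which the authors deposited without normalization. RSEM 1.2.15 and Bowtie2 2.1.0 are named in the submitters' processing notes. RSEM shares reads that fit several genes among them by an estimate, so near-identical copies can exchange counts, and 17.0 to 20.0% of the values per library were not whole (further than 0.005 from a whole number). The same notes name the human build hg38, but 22542 of the 24054 symbols listed are current mouse RefSeq symbols and a further 1372 are mouse synonyms, so the values were treated as mouse genes and no coordinates are given. The annotation used for counting is not given in the sources used here. Totals of expected counts per library ran from 16774300 to 27570700 with saline, 10042800 to 14706100 with OVA and 12317800 to 16914500 with OVA and anti-IL-4Ra. At these depths 3 counts in a library, used as the floor for a gene at 0, correspond to 0.109 to 0.299 CPM (counts scaled by library total). Each replicate pair differed by far more than sampling noise, so every library counted as its own replicate.

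Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr over the groups (15905 of 24054), library totals were scaled by TMM factors, and all 15 libraries entered a single quasi-likelihood fit in edgeR 4.0.16 under R 4.3.3. The 3 comparisons were OVA with isotype control against saline, anti-IL-4Ra with OVA against OVA with isotype control, and anti-IL-4Ra with OVA against saline. Tests were two-sided, p was adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Throughout, an adjusted p of a gene is from this edgeR test. The standard error (SE) of a log2 fold change was taken from the F statistic. CPM are given as mean ± SD over the 5 libraries of a group and use the TMM-scaled totals. A gene with 0 counts in all 5 libraries of a group is given as a lower bound against 3 counts over that group, and a gene with 1 to 3 counts as a ratio with a 95% interval. Intervals and floors cover counting error only. The replicates are labelled as biological, so p-values measure the spread between animals.

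The pipeline was tested on simulated counts with 200 changed genes at the real depths. For OVA against saline, 69 of 100 genes changed by 2-fold and 96 of 100 changed by 4-fold were called among 15828 genes tested. There were 9 false calls, 5.17% of all calls. For anti-IL-4Ra against OVA 60 and 96 were called among 15814 genes tested, with 8 false calls (4.88% of all calls). For anti-IL-4Ra against saline 72 and 93 were called among 15842 genes tested, with 4 false calls (2.37% of all calls). The simulated genes varied independently, without a structure shared among libraries, so these shares of false calls need not hold for the real data.

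A set of 32 gene lists was fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and most of the alternative settings. The lists cover type 2 cytokines and alarmins, IL-4 and IL-13 receptor and signalling genes, goblet cell and mucus genes, alternatively activated macrophage genes, CC chemokines, type 17 and neutrophil-recruiting genes, interferon-gamma response genes, type I interferon response genes, extracellular matrix genes, eicosanoid pathway genes, cell cycle genes, circadian clock genes, and immediate early and heat shock genes. Markers were listed for eosinophils, neutrophils, mast cells and basophils, T cells, T helper 2 and regulatory T cells, B cells, plasma cells, natural killer cells, alveolar macrophages, dendritic cells, club cells, ciliated cells, alveolar type 2 cells, alveolar type 1 cells and endothelial cells, and for cardiac muscle, adipose tissue, red blood cells, and skeletal muscle with upper airway wall. Of 430 entries, 428 were found in the table and 399 were tested. The list entry Clca1 was matched to the symbol Clca3, its older name. The entry Ear11, an older name of Rnase2a, and Ly6g were matched to no symbol by the fixed names, so Rnase2a is given among single genes and not counted in its list. Each list was tested against all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 32 lists of a comparison. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of the list score (the mean log2 CPM of the members in a library, relative to the saline mean), whose smallest possible p with 5 against 5 is 0.00794.

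The rule for named genes took Il4ra first, then per comparison the 8 largest increases and 6 largest decreases among called genes with a mean of at least 1 CPM in a group and no overlap between the groups, leaving out predicted genes and pseudogenes. It also took up to 4 members of a described list with the smallest adjusted p, which could be given in the other comparisons too, and Il4, Il5 and Il13 in every comparison. For the return towards saline it took the 6 genes changed in opposite directions with the smallest adjusted p for the antibody, and the 6 genes still apart from saline with the smallest adjusted p.

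Both the OVA and the antibody effect use the same OVA libraries, so the slope of one on the other was computed with these libraries split 3 to 2 in all 10 ways. The overlap of calls was set beside 20 simulations with neither an OVA nor an antibody effect. The alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors, library totals without TMM, no filter and a stricter filter on low counts (at least 50 in 5 libraries), and robust dispersion. Further ones were fits of 2 groups only, the replicate number as a block, a threshold of 0.01, an absolute log2 fold change of at least 1, and each library left out in turn. Thinning to equal depth, the share of counts on Rn45s (the precursor of ribosomal RNA) as a covariate, removal of Rn45s, the cardiac marker score as a covariate, leaving out the library with the most adipose RNA in each group, and the permutation of list scores were chosen after seeing the data. For each comparison, 100 of the 126 splits of its 10 libraries into 5 and 5 were also fitted.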

Results

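Whole-lung RNA-seq counts were compared among 3 groups of 5 female Balb mice. The saline group was sham-sensitised and given an isotype control antibody. The OVA group was sensitised and challenged with ovalbumin (OVA, the allergen of this asthma model) and given the isotype control, and the anti-IL-4Ra group was treated with OVA and an antibody against IL-4Ra at 30 mg/kg. IL-4Ra is the subunit shared by the receptors for IL-4 and IL-13. Total expected counts per library ran from 16774300 to 27570700 with saline, from 10042800 to 14706100 with OVA and from 12317800 to 16914500 with OVA and anti-IL-4Ra. Between 17923 and 18401 genes were detected per library. The first principal component held 48.7% of the variance and set all saline libraries (-71.1 to -49.0) apart from the OVA (16.3 to 63.0) and anti-IL-4Ra (-10.9 to 48.4) libraries. The share of counts on Rn45s, the precursor of ribosomal RNA, also differed. It was 1.75 ± 0.68% with saline and 7.14 ± 3.36% with OVA (exact permutation p = 0.00794, the smallest possible; adjusted p = 0.0333 over the 21 tests of library measures), and 7.34 ± 4.69% with anti-IL-4Ra, where single libraries ranged from 1.65 to 12.4%.

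**Figure D1:**
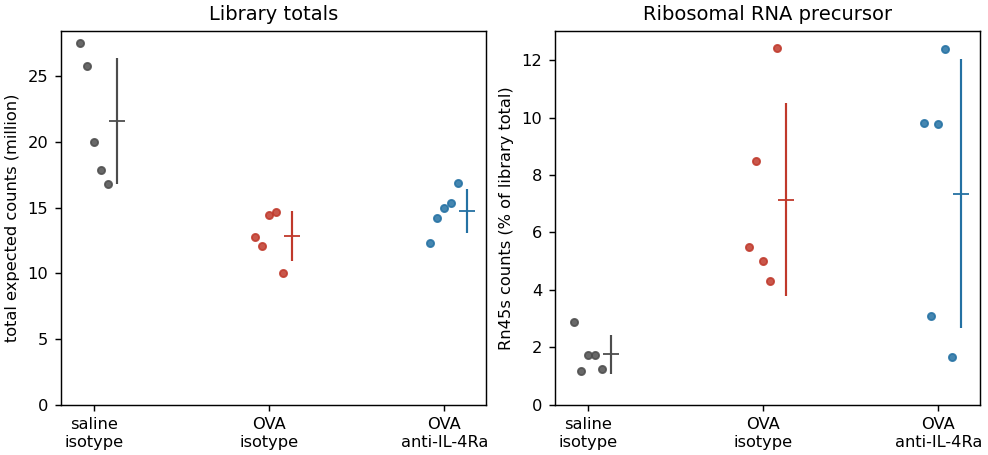
Total expected counts and share of counts on Rn45s in percent for the 15 libraries by group; points are single libraries and bars the mean ± SD. All 5 saline libraries hold at least 16774300 counts and an Rn45s share of at most 2.88%, and all 5 OVA libraries a share of at least 4.31%.

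Il4ra itself, the target of the antibody, was measured at 183 ± 18.6 CPM with saline, 166 ± 14.8 CPM with OVA and 141 ± 26.0 CPM with OVA and anti-IL-4Ra (n = 5 each), with single libraries from 115 to 210 CPM. It was called only between the anti-IL-4Ra and saline groups, where it fell by 0.37 ± 0.12 (log2 ± SE, adjusted p = 0.036). The differences between OVA and saline (-0.14 ± 0.12, adjusted p = 0.39) and between anti-IL-4Ra and OVA (-0.23 ± 0.12, adjusted p = 1) passed no threshold. The call against saline was lost without saline replicate 3, 4 or 5 and without anti-IL-4Ra replicate 1, 3 or 5 (adjusted p up to 0.10). It was also lost with the Rn45s share (-0.33 ± 0.17, adjusted p = 0.30) or the cardiac score (-0.49 ± 0.16, adjusted p = 0.072) as a covariate, at changes of like size.

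The comparison of OVA with saline, both under the isotype control, addresses what the asthma model changes in the lung. In OVA lungs, genes of mucus-secreting goblet cells, of alternatively activated macrophages, of chemokines and of dividing cells rose, and markers of endothelium, alveolar epithelium and club cells fell. Clca3, an older symbol of Clca1 and a secreted component of airway mucus, went from 0.814 ± 1.34 to 5818 ± 4319 CPM, a log2 change of 12.91 ± 1.32 (± SE, n = 5 per group, adjusted p = 1.6e-05). Arg1, the arginase of alternatively activated macrophages, went from 2.34 ± 0.738 to 152 ± 59.7 CPM (6.03 ± 0.41, adjusted p = 5.1e-07). Cdh5, the cadherin of endothelial junctions, went from 1139.6 ± 136 to 377 ± 132 CPM (-1.59 ± 0.32, adjusted p = 0.0015). Altogether 5898 of 15905 tested genes were called (37.1%), 3069 higher and 2829 lower, and 2261 of them by at least 2-fold (1487 higher, 774 lower). In 4235 genes (26.6%) the 5 OVA and the 5 saline libraries did not overlap, against 0.794% by chance.

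The fixed rule admits only called genes without overlap between the groups. Its 8 largest increases were led by Chil4, a chitinase-like protein of allergic lungs, at 13.83 ± 1.49 (0.164 ± 0.319 to 2079.6 ± 1428 CPM). Retnlb, a resistin-like protein of goblet cells, had 1768 counts with OVA and 0 with saline, at least 977-fold higher against 3 counts over the group. Mrgprg, a G protein-coupled receptor, had 517 against 0 counts, at least 286-fold higher. Sprr2a1, an epithelial cornification gene, had 4931 against 3 counts, a ratio of 2726 (95% interval 932 to 13224). Sprr2a2 carried identical values in all 15 libraries, so these copies could not be separated. Rnase2a, an eosinophil-associated ribonuclease also called Ear11, rose by 9.20 ± 0.68 to 92.8 ± 41.7 CPM and the calpain protease gene Capn9 by 8.40 ± 1.11; Rnase2a belongs to a family of similar copies that may exchange reads. The largest decreases were in Crb1, an apical polarity gene (-4.82 ± 0.75), Pon1, a paraoxonase (-3.95 ± 0.54), Asgr1, an asialoglycoprotein receptor subunit (-3.93 ± 0.65), Fabp1, a fatty acid binding protein (-3.72 ± 0.46), Vstm2a (-3.64 ± 0.53) and the non-coding BC055402 (-3.57 ± 0.59), with adjusted p from 5.8e-05 to 0.00044. With OVA, Asgr1, BC055402, Crb1 and Vstm2a rested on 4 to 10 counts over the group.

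Of the functional lists, 15 of 16 goblet cell and mucus genes were higher with OVA (15 adjusted over the list alone), with a median log2 change of 5.98 that is the same with Retnlb at its bound. Beside Clca3 they included Fcgbp, an IgG Fc binding protein of mucus (7.47 ± 0.93), Itln1, intelectin (7.11 ± 0.75), and Slc26a4, the anion exchanger pendrin (5.93 ± 0.57). The camera test gave an adjusted p of 9.4e-15 and an adjusted p = 0.157 with an estimated correlation. Alternatively activated macrophage genes were higher in 16 of 19 and lower in 2 (16 and 3 adjusted over the list alone), as in Retnla, a resistin-like protein (8.15 ± 0.64), and Pdcd1lg2, the ligand PD-L2 (4.25 ± 0.28). All 9 tested CC chemokines were higher (9 adjusted over the list alone), including Ccl8 (6.08 ± 0.41), Ccl24 (3.69 ± 0.41), Ccl22 (3.32 ± 0.31) and Ccl9 (2.31 ± 0.22). Both lists kept an adjusted p of 0.0202 with an estimated correlation. Of 6 type 2 cytokines and alarmins, 4 were higher and 1 lower, with the same counts adjusted over the list alone and a camera adjusted p of 0.0687 (0.418 with an estimated correlation). They were Il13 (4.73 ± 0.75), Il4 (2.58 ± 0.59) and Il5 (2.57 ± 0.54), the cytokines of T helper 2 cells, and the epithelial alarmin Il33 (0.95 ± 0.23); Il4 stayed at 0.915 ± 0.476 CPM. Of 25 cell cycle genes 24 were higher (25 adjusted over the list alone), such as the topoisomerase Top2a (2.97 ± 0.28) and the ribonucleotide reductase subunit Rrm2 (3.09 ± 0.31), with an adjusted p = 0.110 with an estimated correlation.

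Smaller shares changed in the remaining functional lists. Of 12 IL-4 and IL-13 receptor and signalling genes 4 were higher and 1 lower (5 and 1 adjusted over the list alone), including the feedback inhibitor Socs1 (1.54 ± 0.27). Of 22 extracellular matrix genes 9 were higher, such as osteopontin Spp1 (2.31 ± 0.32), the protease inhibitor Timp1 (2.39 ± 0.30) and the collagen gene Col3a1 (1.03 ± 0.23). Of 15 eicosanoid pathway genes 4 were higher, among them the lipoxygenase Alox15 (3.05 ± 0.43). Of 7 type 17 and neutrophil-recruiting genes 4 were higher and 1 lower, with Cxcl5, a neutrophil chemokine, at 2.84 ± 0.54 and Saa3, an acute phase protein, at 1.60 ± 0.43. Counts adjusted over the list alone were the same in these 3 lists. Of 17 type I interferon response genes 10 were lower and 1 higher (11 and 1 adjusted over the list alone), with Ifit2 at -1.02 ± 0.23 and Mx1 the member that rose (1.59 ± 0.26). Interferon-gamma response genes were mixed, with 2 of 22 higher, the chemokine Cxcl9 (2.34 ± 0.55) and the antigen presentation regulator Ciita (1.68 ± 0.31), and 5 lower, in the same numbers adjusted over the list alone; the median (-0.07) and mean (0.12) of this list differ in sign. Camera called the type 17, matrix and type I interferon lists (adjusted p 0.0425, 0.0066 and 0.00385), each at an adjusted p = 0.418 with an estimated correlation. Among genes that follow sampling, 1 of 12 circadian clock genes was lower (Nr1d1, 2.83-fold), and of 13 immediate early and heat shock genes 4 were lower, including Jun (-0.86 ± 0.18), and 1 was higher, again with equal counts adjusted over the list alone.

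Markers of immune cells moved in both directions. Of 7 eosinophil markers 4 were higher and 2 lower (5 and 2 adjusted over the list alone). Among them were the chemokine receptor Ccr3 at 3.78 ± 0.41, the granule protein Prg2 at 5.45 ± 0.72, the receptor Il5ra at 1.61 ± 0.32, and the peroxidase Epx at 115 against 3 counts, a ratio of 63.6 (95% interval 21.2 to 313). The 2 lower eosinophil markers were Ear1 and Siglec5, the symbol found for Siglecf. Ear1 had 280 to 383 counts per library with saline and 5 to 85 with OVA, not scaled for depth. Siglec5 had 198 to 291 and 58 to 124. T cell markers were higher in 11 of 13 (11 adjusted over the list alone), as in Cd4 (1.84 ± 0.33) and Icos (2.49 ± 0.26). Markers of T helper 2 and regulatory T cells were higher in 10 of 12 (10 higher and 1 lower adjusted over the list alone), as in Ctla4 (3.17 ± 0.23) and the IL-33 receptor Il1rl1 (1.77 ± 0.21). B cell markers were higher in 10 of 10 (10 adjusted over the list alone). Plasma cell genes were higher in 9 of 12 and lower in 1 (the same adjusted over the list alone), with Mzb1 at 3.73 ± 0.61 and the transcription factor Irf4 at 2.58 ± 0.41. Dendritic cell markers were higher in 8 of 12 (8 higher and 1 lower adjusted over the list alone). Natural killer cell markers were lower in 5 of 9 (6 adjusted over the list alone), such as Gzma (-1.20 ± 0.33) and Prf1 (-1.18 ± 0.27), genes of cytotoxic granules. Neutrophil markers were lower in 6 and higher in 2 of 13 (7 and 3 adjusted over the list alone). They included the receptor Trem1 at -1.66 ± 0.34, Retnlg at 3.28 ± 0.43 and the decoy receptor Il1r2 at 2.08 ± 0.27. Mast cell and basophil markers were higher in 3 and lower in 2 of 12, with the protease Mcpt1 at 4.43 ± 0.47. Alveolar macrophage markers were higher in 3 and lower in 3 of 11, with Itgax (2.05 ± 0.17) and Ctsk (2.39 ± 0.24) up and Fabp1 down. Both lists had the same counts adjusted over the list alone. The alveolar macrophage list has a negative median (-0.18) and an upward camera direction (adjusted p = 0.688). Of the camera calls for immune lists, the T helper 2 and regulatory T cell list kept one with an estimated correlation (adjusted p = 0.0202). The adjusted p was 0.20 for eosinophils, 0.133 for dendritic cells, and 0.418 for T cells, B cells, plasma cells and natural killer cells.

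Markers of endothelium, alveolar epithelium and club cells were lower in OVA lungs, and most ciliated cell markers were not called. Of 14 endothelial markers 13 were lower (13 adjusted over the list alone), as in Kdr, the VEGF receptor 2 gene (-1.49 ± 0.23). Of 10 alveolar type 1 cell markers 9 were lower (10 adjusted over the list alone), as in the receptor Ager (-1.28 ± 0.25) and the water channel Aqp5 (-1.56 ± 0.27). Alveolar type 2 cell markers were lower in 7 and higher in 1 of 11 (the same adjusted over the list alone), with the surfactant protein gene Sftpb at -1.62 ± 0.30 and the lipid transporter Abca3 at -0.75 ± 0.15. Club cell markers were lower in 9 of 12 (9 lower and 1 higher adjusted over the list alone), with the cytochrome P450 Cyp2f2 at -2.75 ± 0.41 and haptoglobin Hp at -1.70 ± 0.22. Of 15 ciliated cell markers 2 were lower (2 adjusted over the list alone), including Tppp3 (-1.53 ± 0.25), and the list's median was 0.21. The camera calls for these structural lists, apart from ciliated cells, were not kept with an estimated correlation (adjusted p = 0.376 for endothelium and for alveolar type 1 cells, 0.418 for type 2 cells and 0.389 for club cells). Red blood cell genes were lower in 7 of 8 (8 adjusted over the list alone; adjusted p = 0.418 with an estimated correlation), as in Alas2, the erythroid enzyme of haem synthesis (-1.48 ± 0.44). Of 11 cardiac muscle markers 1 was lower, Myh7 (-1.36 ± 0.20), also when adjusted over the list alone. Whether RNA of these markers came from heart tissue or from the lung itself was not tested. Myh7 did not always follow other members. Saline replicates 1 and 2 had 4554 and 4697 counts of Myh7 but 3313 and 1004 of Myl7. Anti-IL-4Ra replicate 1 had 939 of Myh7 with 15 of Myl7 and 0 of Sln. The fall of Myh7 alone is therefore no sign of less cardiac muscle. No adipose (7 tested) or skeletal muscle and airway wall (5 tested) marker was called by edgeR, DESeq2 or voom, and none had an unadjusted edgeR p under 0.05. The skeletal muscle list has a median of 0.21 and a downward camera direction (adjusted p = 0.981). Adipose genes varied widely, with Adipoq at 9.78 ± 18.2 CPM with OVA and 57.3 CPM with saline, where single libraries ranged from 0.101 to 233 CPM.

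The Rn45s share, which was higher in every OVA library than in every saline library, moved with all of these groups. With its log2 value as a covariate, 752 genes were called between OVA and saline (486 higher, 266 lower). Among these were 12 goblet cell genes, 15 alternatively activated macrophage genes, 8 CC chemokines, 17 cell cycle genes, 5 type 17, 4 matrix, 2 eicosanoid and 2 type 2 cytokine genes and 1 type I interferon gene as higher, and 0 members of these lists as lower (3 type I interferon genes and 1 eicosanoid gene at an unadjusted p under 0.05). Il4 (1.39 ± 0.77, adjusted p = 0.267) and Il5 (2.39 ± 0.76, adjusted p = 0.0802) lost their calls. So did Mrgprg, Asgr1 (-2.61), BC055402 (-2.79) and Cdh5 among the genes given above, Socs1, Col3a1, Ifit2, Cxcl9, Ciita, Nr1d1 and Jun of the functional lists, and Il5ra, Cd4, Mzb1, Irf4, Gzma, Prf1, Trem1, Ager, Aqp5, Sftpb, Abca3, Tppp3 and Alas2 of the markers. Mrgprg aside, which had 0 counts with saline, Cxcl9 alone of these did not become smaller (2.34 ± 0.55 to 2.56 ± 0.73, adjusted p = 0.0578). The others shrank, such as Cdh5 from -1.59 ± 0.32 to -0.67 ± 0.29 and Gzma from -1.20 ± 0.33 to -0.17 ± 0.32. The lists of interferon-gamma response, IL-4 and IL-13 signalling, clock and immediate early genes had 0 calls by edgeR among 59 members, with 7 higher and 9 lower at an unadjusted p under 0.05. Of the immune cell markers, 6 of T helper 2 and regulatory T cells, 4 of eosinophils, 3 of dendritic cells, 3 of alveolar macrophages, 2 of neutrophils, 2 of mast cells and basophils and 1 of T cells were called higher. Called lower were 3 club cell markers and 1 each of endothelium, alveolar type 2 cells, alveolar macrophages and cardiac muscle. The other 8 lists of cell and tissue markers had 0 calls by edgeR among their 76 members, with 6 higher and 13 lower at an unadjusted p under 0.05.

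**Figure D2:**
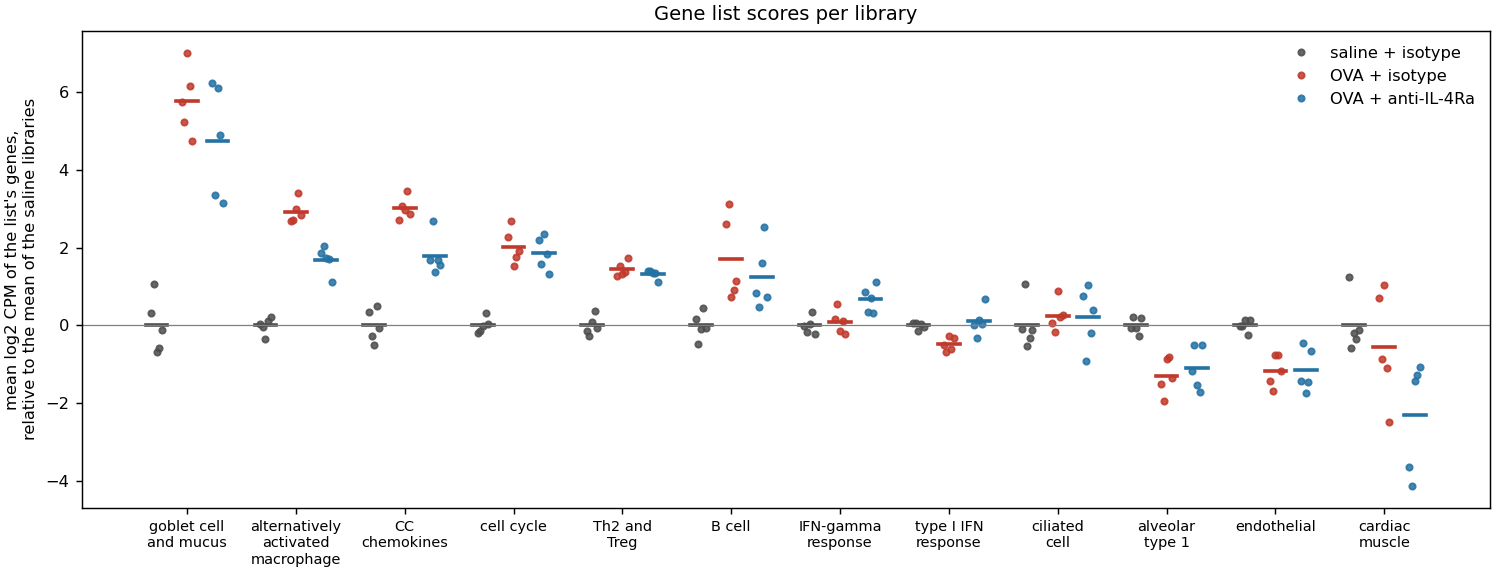
Scores of gene lists in the 15 libraries, each the mean log2 CPM of the list's members relative to the saline mean, by group; points are single libraries. Goblet cell scores reach 4.75 to 7.01 with OVA and 3.15 to 6.23 with OVA and anti-IL-4Ra, and stay at or below 1.08 with saline.

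The comparison of anti-IL-4Ra with isotype control in OVA mice addresses what blocking the receptor changes in the challenged lung. Part of the genes of alternatively activated macrophages (5 of 19) and of the CC chemokines (3 of 9) were called lower, and single genes such as Fpr1 and Fpr2 rose. Arg1 fell from 152 ± 59.7 to 7.62 ± 4.41 CPM, a log2 change of -4.32 ± 0.38 (n = 5 per group, adjusted p = 6.8e-05), and Ccl24, the eosinophil chemoattractant eotaxin-2, fell from 19.8 ± 6.92 to 1.27 ± 0.845 CPM (-3.95 ± 0.43, adjusted p = 0.00045). Fpr1 and Fpr2, formyl peptide receptors of phagocytes, were higher by 3.06 ± 0.44 (adjusted p = 0.0026) and 2.63 ± 0.32 (adjusted p = 0.00082). In all, 48 of 15905 genes were called, 22 higher and 26 lower, and 41 of them by at least 2-fold (15 higher, 26 lower). DESeq2 called 128 genes, among them all 48, and limma-voom called 51. At an unadjusted p under 0.05 there were 903 genes, and 186 genes (1.17%) had no overlap between the groups, against 0.794% by chance.

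The largest decreases under the antibody were in Rnase2a (-5.75 ± 0.54, from 92.8 ± 41.7 to 1.74 ± 1.79 CPM), Arg1 and Ccl24. They were followed by the homeobox gene Msx3 (-3.83 ± 0.48), Ocstamp, a transmembrane protein of macrophage and osteoclast fusion (-3.23 ± 0.37), and the helicase Ddx4 (-3.12 ± 0.38). By the fixed rule, which leaves out symbols such as 1100001G20Rik (1.71 ± 0.33), the largest increases began with Fpr1, Vstm2a (2.94 ± 0.55) and Fpr2. Next were Fcgr1, the high-affinity IgG receptor (1.84 ± 0.22), and the paired inhibitory receptor Pilra (1.64 ± 0.22). Further ones were Mcemp1, a membrane protein of myeloid cells (1.51 ± 0.18), the lectin-like receptor Klrb1b (2.82-fold) and the potassium channel Kcnn3 (1.45 ± 0.20). The rule admits only called genes without overlap between the groups, so all 14 had none, and their adjusted p ran from 6.8e-05 to 0.0277.

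Alternatively activated macrophage genes were lower in 5 of 19 (10 adjusted over the list alone), among them Dcstamp, another fusion protein (-2.45 ± 0.37), the lectin Mgl2 (-2.19 ± 0.27) and Pdcd1lg2 (-1.79 ± 0.25). Retnla, Chil3, Chil4 and the mannose receptor gene Mrc1 of this list were not called. The list kept its camera call with an estimated correlation (adjusted p = 0.00236). CC chemokines were lower in 3 of 9 (5 adjusted over the list alone; adjusted p = 0.0226 with an estimated correlation), namely Ccl24, Ccl11, the chemokine eotaxin-1 (-2.61 ± 0.48), and Ccl9 (-1.05 ± 0.21). Ccl8 was at -1.19 ± 0.32 (adjusted p = 0.23) and Ccl22 at -0.81 ± 0.29 (adjusted p = 0.56). In both lists the scores of the anti-IL-4Ra libraries lay below all OVA scores (exact permutation p = 0.00794, the smallest possible; 0.127 adjusted over the 32 lists).

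Interferon response genes had no member called by edgeR, although camera set both lists above other genes. Of 22 interferon-gamma response genes, 17 were higher at an unadjusted p under 0.05, 14 were higher and 1 lower adjusted over the list alone. DESeq2 called 6 higher and voom none, with an adjusted camera p = 0.0471 with an estimated correlation. The members with the smallest p were the GTPase Gbp3 (0.77 ± 0.16, adjusted p = 0.056) and the chemokine Cxcl10 (1.61 ± 0.37, adjusted p = 0.11). Of 17 type I interferon response genes, 15 were higher at an unadjusted p under 0.05 and 15 adjusted over the list alone, DESeq2 called 2 and voom none (adjusted p = 0.0263 with an estimated correlation). The score of either list overlapped between the groups. The interferon-gamma score reached 0.558 with OVA and started at 0.329 with anti-IL-4Ra (exact permutation p = 0.0317, and 0.254 adjusted over the 32 lists). The type I score reached -0.266 and started at -0.314 (exact permutation p = 0.0159, and 0.169 adjusted). Irf7, a regulator of the response, was at 1.04 ± 0.22 (adjusted p = 0.067) and Isg15 at 0.83 ± 0.19 (adjusted p = 0.11).

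Goblet cell and mucus genes had values below 0 in 16 of 16 (median -0.66), but none was called by edgeR, DESeq2 or voom and none adjusted over the list alone. At an unadjusted p under 0.05, 2 were lower, Itln1 (-1.85 ± 0.56, adjusted p = 0.39) and Retnlb (-1.84 ± 0.66, adjusted p = 0.62). The camera adjusted p of 1.1e-05 became 0.388 with an estimated correlation, and the score differed by -1.03 with SDs of 1.46 and 0.865 (exact permutation p = 0.238, and 0.571 adjusted over the 32 lists). Il13 (0.18 ± 0.55), Il5 (0.26 ± 0.47) and Il4 (-0.35 ± 0.51) were not called (adjusted p = 1 each). Eosinophil markers had no call (edgeR unadjusted p under 0.05 in 2 higher and 3 lower, DESeq2 1 lower, voom none; 2 higher and 3 lower adjusted over the list alone). Epx was at -2.63 ± 0.55 (adjusted p = 0.066) and Prg2 at -1.84 ± 0.57 (adjusted p = 0.40). The 2 higher eosinophil markers were Ear1 and Siglec5. Cardiac muscle markers had no call either, but 9 of 11 were lower at an unadjusted p under 0.05 and adjusted over the list alone (DESeq2 1, voom none; adjusted p = 0.198 with an estimated correlation). Myl4 was at -2.04 ± 0.67 (adjusted p = 0.48).

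edgeR called no member of any of the 30 lists other than macrophage genes and CC chemokines. Counted list by list, 56 of their 371 members were higher and 33 lower at an unadjusted p under 0.05, DESeq2 called 11 higher and 7 lower, and voom called 0 higher and 1 lower. Camera set 18 of the 32 lists apart from other genes, and 4 of them with an estimated correlation. Of 48 calls, 30 were kept with each library left out in turn. Among named genes, Ccl9 lost its call in 13 of these fits (adjusted p up to 0.13), Ccl11 in 7 (0.077), Vstm2a in 5 (0.097) and Klrb1b in 4 (0.058). With the cardiac score as a covariate Ccl11 and Klrb1b lost it too (0.0907 and 0.158). Ccl11 went from -2.608 ± 0.476 to -2.750 ± 0.605 and Klrb1b from 1.498 ± 0.261 to 1.273 ± 0.311. The change of Ccl11 was thus not smaller, that of Klrb1b was somewhat smaller, and both errors were larger. Without the libraries with the most adipose RNA, Ccl9 and Vstm2a lost the call. The count of higher genes fell to 13 without OVA replicate 1 and to 14 without anti-IL-4Ra replicate 5. Other splits of the same 10 libraries gave as many calls or more in 4 of 99 cases, and the highest gave 1314.

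**Figure D3:**
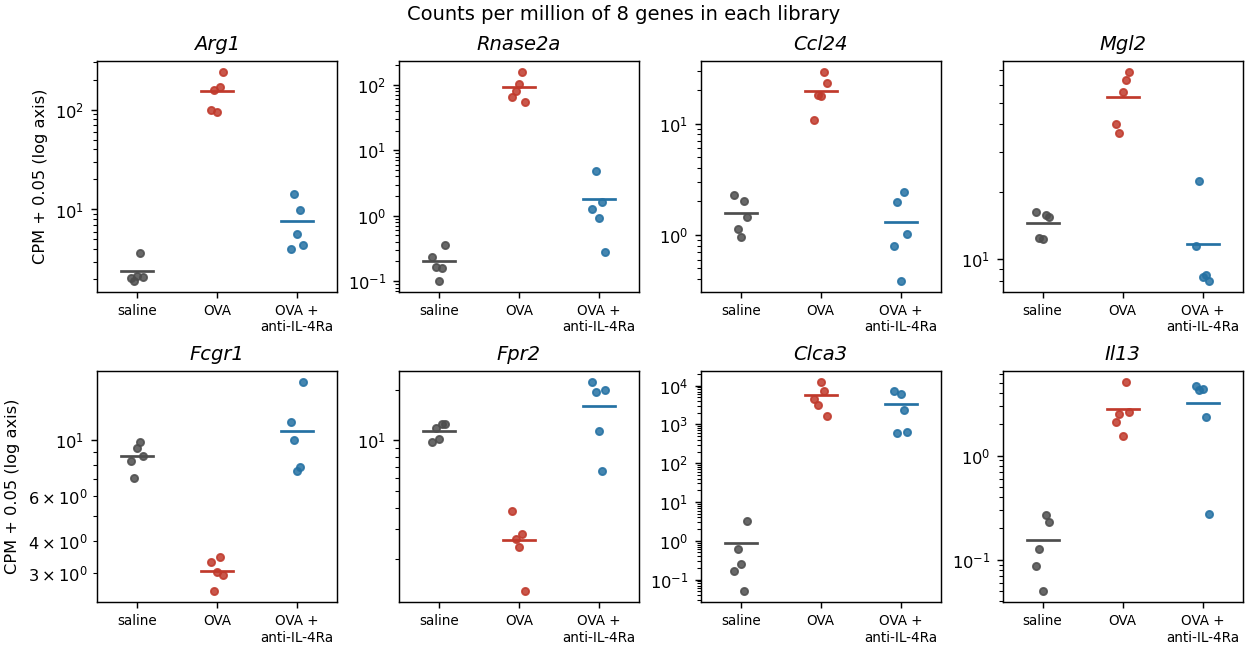
CPM of 8 named genes in the 15 libraries on a log axis (0.05 CPM added), by group, with points for single libraries and bars for group means. Arg1 and Ccl24 in the anti-IL-4Ra group lie below all OVA libraries, while Clca3 overlaps between both OVA groups.

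The comparison of anti-IL-4Ra OVA mice with saline mice addresses what of the model remained under the antibody. Mucus genes, cell cycle genes, T cell markers and most chemokines were still higher than with saline, and endothelial and alveolar type 1 cell markers still lower. With the Rn45s share as a covariate, the called mucus genes went from 15 to 4, cell cycle genes from 22 to 14, T cell markers from 11 to 1 and CC chemokines from 7 to 6. At an unadjusted edgeR p under 0.05, 14 of 16 mucus genes, 22 of 25 cell cycle genes, 7 of 13 T cell markers and 7 of 9 CC chemokines were still higher, and 0 lower. Endothelial markers went from 12 and alveolar type 1 markers from 9 to 0 by edgeR (8 and 2 lower at an unadjusted p under 0.05). The camera calls of these 6 lists were not kept with an estimated correlation (adjusted p from 0.117 to 0.268). Clca3 was at 3419.6 ± 3151 CPM (12.14 ± 1.29, adjusted p = 7e-05), Retnla at 4681 ± 2876 CPM (7.69 ± 0.62, adjusted p = 8.1e-06) and Ctla4 at 7.26 ± 1.49 CPM (3.29 ± 0.23, adjusted p = 3.2e-06). There were 4236 calls, 2211 higher and 2025 lower, 1632 of them by at least 2-fold (1174 higher, 458 lower), and 3151 genes (19.8%) without overlap, against 0.794% by chance.

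The largest increases by the fixed rule were the mucus and macrophage genes Clca3, Chil4 (11.29 ± 1.41), Muc5ac, the main gel-forming airway mucin (8.09 ± 1.18), and Retnla, with Capn9 (7.85 ± 1.11). Retnlb had 548 against 0 counts, at least 264-fold higher, and Sprr2a1, inseparable from Sprr2a2, had 2566 against 3 counts, a ratio of 1234 (95% interval 422 to 5988). The largest decreases by the same rule were BC055402 (-3.25 ± 0.55), Hamp, which encodes hepcidin (-2.81 ± 0.85), and 4 genes of striated muscle. The latter were the sarcoplasmic reticulum regulator Sln (-2.98 ± 0.84), myoglobin Mb (-2.97 ± 0.97), Dhrs7c (-2.86 ± 0.78) and the potassium channel Kcnj3 (-2.82 ± 0.85). Calls were lost without single libraries for Mb (saline 1 or 5, anti-IL-4Ra 1 or 3; adjusted p up to 0.11), Hamp (anti-IL-4Ra 1 or 3; 0.060), Kcnj3 (saline 1 or anti-IL-4Ra 1; 0.085) and Sln (saline 1; 0.053). With the Rn45s share as a covariate all 6 decreases (-2.51 to -3.24, adjusted p from 0.0552 to 0.206), Muc5ac (6.20, adjusted p = 0.0516) and Capn9 (5.74, adjusted p = 0.0501) lost the call. With the cardiac score the decreases other than BC055402 lost it, at -0.17 to -0.85. Sln is itself a member of the cardiac list, so the score takes off part of its own change by construction.

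Goblet cell and mucus genes were higher in 15 of 16 (15 adjusted over the list alone; adjusted p = 0.144 with an estimated correlation). In the same terms, cell cycle genes were higher in 22 of 25 (22; 0.117), CC chemokines in 7 of 9 (7; 0.117) with Ccl8 at 4.89 ± 0.39, and T cell markers in 11 of 13 (11; 0.228). Markers of T helper 2 and regulatory T cells were higher in 10 of 12 (10 adjusted over the list alone) and kept the camera call with an estimated correlation (adjusted p = 0.0220). Alternatively activated macrophage genes were higher in 11 and lower in 2 of 19 (13 and 2 adjusted over the list alone; adjusted p = 0.144 with an estimated correlation), with Chil3, another chitinase-like protein, at 3.68 ± 0.48. Il13 (4.91 ± 0.75), Il5 (2.82 ± 0.53) and Il4 (2.23 ± 0.60) were higher. Il5 lost its call with the Rn45s share (2.65 ± 0.72, adjusted p = 0.0651) and the cardiac score (1.74 ± 0.56, adjusted p = 0.0612) as a covariate. Il4 lost it with both (1.06 ± 0.76 and 1.67 ± 0.75), without the libraries with the most adipose RNA and at a threshold of 0.01. Of 12 circadian clock genes 2 were higher and 4 lower by edgeR, DESeq2 and voom alike, where edgeR called 26.6% of all genes. Npas2 (-1.50 ± 0.39), Arntl (-1.12 ± 0.26) and Nr1d1 (-1.05 ± 0.28) were among the lower and Per3 (0.83 ± 0.24) among the higher ones. The timing of tissue collection is not given in the sources used here, so its part was not tested. Interferon-gamma response genes were higher in 7 of 22 (10 higher and 1 lower adjusted over the list alone; adjusted p = 0.537 with an estimated correlation), with Cxcl9 at 4.26 ± 0.57. Type 17 and neutrophil-recruiting genes were higher in 6 of 7 (6; adjusted p = 0.144), with Saa3 at 3.00 ± 0.44. Endothelial markers were lower in 12 of 14 (13 adjusted over the list alone; adjusted p = 0.228 with an estimated correlation). Alveolar type 1 markers were lower in 9 of 10 (9; 0.268) and club cell markers in 3 of 12 (6; 0.537), with Cyp2f2 at -1.54 ± 0.40, not called with either covariate.

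Cardiac muscle markers were lower in 7 of 11 (9 adjusted over the list alone, camera adjusted p = 0.339 with an estimated correlation), with Myl4 at -2.45 ± 0.68 and Myh7 at -0.97 ± 0.19. Neither was called with the Rn45s share as a covariate (Myl4 -2.33 ± 0.91, Myh7 -0.64 ± 0.23) or with the cardiac score (Myl4 -0.37 ± 0.26, Myh7 -0.77 ± 0.25). Both are members of the cardiac list, so the score takes off part of their own change by construction. With the cardiac score as a covariate the comparison had 1438 calls (878 higher, 560 lower). That score was lower in every anti-IL-4Ra library (-4.12 to -1.06) than in every saline library (-0.58 to 1.24). Calls lost with it therefore cannot tell cardiac muscle content from the treatment. With the Rn45s share as a covariate the comparison had 373 calls (322 higher, 51 lower). Among the higher ones were 14 cell cycle genes, 7 alternatively activated macrophage genes, 6 CC chemokines, 5 type 17 genes, 4 goblet cell genes, 2 each of interferon-gamma response, matrix and eicosanoid genes, 1 type 2 cytokine and 1 clock gene; 1 clock gene was lower. Of the markers, 4 of T helper 2 and regulatory T cells, 2 each of mast cells and basophils, alveolar macrophages and dendritic cells, and 1 each of eosinophils, neutrophils, T cells and plasma cells were called higher. The lists of IL-4 and IL-13 signalling, type I interferon and immediate early genes had 0 calls by edgeR among 42 members, with 3 higher and 2 lower at an unadjusted p under 0.05. The lists of endothelial, alveolar type 1, alveolar type 2, club, ciliated, B and natural killer cells, cardiac muscle, adipose tissue, red blood cells and skeletal muscle had 0 calls by edgeR among 112 members, with 2 higher and 25 lower at an unadjusted p under 0.05.

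Whether the antibody moved the OVA changes back towards saline was asked of both effects together. The 6 genes changed in opposite directions with the smallest adjusted p were Arg1, Rnase2a, Ocstamp, Fcgr1, Mcemp1 and Ccl24. Of these, Ccl24 (-0.26 ± 0.42 against saline, adjusted p = 0.68), Fcgr1 (0.33 ± 0.20, adjusted p = 0.23) and Mcemp1 (0.40 ± 0.17, adjusted p = 0.095) were not called against saline, while Rnase2a (3.45 ± 0.74), Ocstamp (1.99 ± 0.46) and Arg1 (1.71 ± 0.37) were still called higher. Ocstamp (2.13 ± 0.59) and Arg1 (1.53 ± 0.48) lost this call with the Rn45s share as a covariate (adjusted p = 0.0732 and 0.117). With the cardiac score Rnase2a (2.69 ± 0.89), Ocstamp (1.66 ± 0.55) and Arg1 (0.99 ± 0.37) all lost it (adjusted p from 0.0707 to 0.108). That score did not overlap between the anti-IL-4Ra and saline libraries, so these losses cannot tell cardiac muscle content from the treatment. The genes still furthest from saline by adjusted p were Ctla4, Ccl8, Retnla, the inhibitory Fc receptor gene Fcgr2b (1.79 ± 0.15), the co-stimulatory receptor gene Tnfrsf9 (3.24 ± 0.28) and Top2a (2.80 ± 0.28). Of the 48 antibody calls, 25 were higher with OVA and lower with the antibody (5.02 for independent lists), 14 lower and then higher (3.91), 1 was higher in both (4.25), and 8 were not called with OVA. The OVA and antibody comparisons share the OVA libraries with opposite sign, which alone raises overlaps in opposite directions above the independent counts. Of the 39 that changed back, 23 were not called against saline, 14 stayed on the side of the OVA change and 2 were on the other side. Conversely 1951 genes higher with OVA and 1823 lower with OVA were called on the same side against saline in the anti-IL-4Ra group (427 and 360 for independent lists). Both comparisons use the same saline libraries, which alone raises these overlaps above the independent counts, and their size without a remaining effect was not computed.

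Across genes called with OVA, the slope of the antibody effect on the OVA effect was -0.14 (mean over 10 splits of the OVA libraries, SD 0.08, range -0.25 to 0.00), where -1 is full return, and -0.20 without the split. Because the OVA libraries enter both effects, the correlation of the log2 changes across genes, which are not independent replicates, was also simulated. It was -0.514 in the data and -0.265 on average with the OVA libraries split (-0.478 to about 0). With no effect it was -0.513 ± 0.0161 (SD of 20 simulations). The simulated groups lack the OVA effect too, so this value and that in the data are not comparable, and their match decides nothing. The covariance was -0.154 against -0.0403 with no effect, a difference of -0.114, and -0.125 on average with the OVA libraries split (-0.229 to about 0). Opposite calls numbered 39 in the data and 22.7 on average with the split (6 to 72). The simulations gave 0.05, but with neither effect present few genes can be called in either comparison. That value is therefore no measure of a return, and a simulation that keeps the OVA effect was not run.

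**Figure D4:**
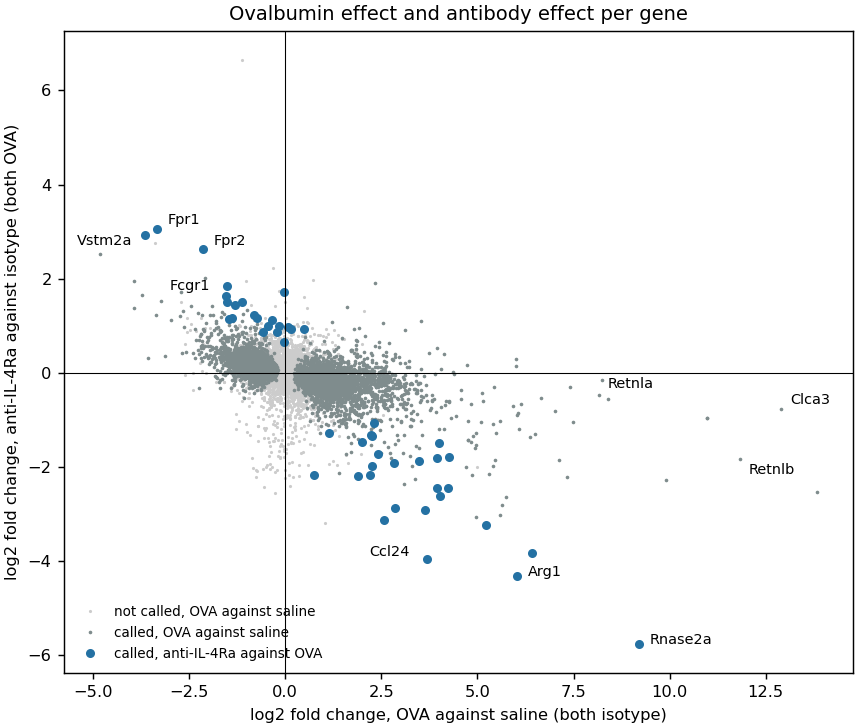
Log2 fold change of anti-IL-4Ra against OVA (vertical) over that of OVA against saline (horizontal) for all 15905 tested genes, with the genes called for the antibody marked and some named. Of the 48 marked genes 39 were also called with OVA in the opposite direction. The axes share the OVA libraries, which gave a correlation of -0.513 in simulations with neither an OVA nor an antibody effect. That value is not comparable with the correlation in the plotted data, which hold an OVA effect.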

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

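The tests of depth, the Rn45s share (in both patterns), airway content, exchanged labels and dilution below were chosen only after the result was seen; the test of GC content and transcript length was chosen before.

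In groups of 5 libraries, a library was listed when its gap to the nearest of the others took more than 0.71 of the group's range (Dixon's 95% critical value). This held in 43 of 421 groups tested, over library measures, list scores and 102 single genes, where chance gives about 21.1; the genes are correlated, so the excess is not itself a test. Of the 43, 20 were in saline, 10 in OVA and 13 in anti-IL-4Ra libraries.

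Saline replicate 1 stood above the other saline libraries in genes of heart muscle and fat. Its cardiac muscle score was 1.24, with Myl4 at 130.1 CPM, Mb at 49.9 CPM, Sln at 18.2 CPM, Kcnj3 at 7.38 CPM and Dhrs7c at 5.95 CPM, and its Adipoq was at 233 CPM and Ccl11 at 4.18 CPM. Adipoq was also far above the group in OVA replicate 1 (42.3 CPM) and anti-IL-4Ra replicate 4 (78.0 CPM). Saline replicate 2 was highest for the club cell score (0.96), the ciliated cell score (1.06), Retnla (48.2 CPM), Ctsk (22.4 CPM) and Muc5ac (7.40 CPM). Among the other saline libraries, replicate 3 was high for Ocstamp (0.252 CPM), replicate 4 for Saa3 (33.2 CPM), Mx1 (8.28 CPM) and Arg1 (3.65 CPM), and replicate 5 for Clca3 (3.18 CPM), Vstm2a (2.56 CPM) and Chil4 (0.733 CPM).

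Among OVA libraries, replicate 2 was highest for the T cell score (2.26), Cd4 (78.7 CPM), Ccl22 (60.3 CPM) and Cxcl9 (17.5 CPM). Replicate 3 was highest for Nr1d1 (119 CPM), replicate 4 for Ccl9 (206 CPM), and replicate 5 for Mx1 (28.4 CPM), Prg2 (21.6 CPM) and Epx (4.51 CPM). Among anti-IL-4Ra libraries, replicate 2 was highest for the CC chemokine score (2.68), Timp1 (33.0 CPM), Mgl2 (22.2 CPM) and Rnase2a (4.82 CPM). Replicate 4 was highest for Col3a1 (2435 CPM) and Alox15 (31.5 CPM) and lowest for the share of counts on Malat1 (1.42%). Replicate 5 was highest for Cyp2f2 (1725 CPM), Pon1 (33.6 CPM), Crb1 (1.25 CPM) and Asgr1 (1.08 CPM), and lowest for the score of T helper 2 and regulatory T cell markers (1.12).

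The 5898 genes called between OVA and saline came with shallower OVA libraries and a higher Rn45s share. After thinning to equal depth 89.9% of them were still called, which argues against depth as the main cause. The trend with the Rn45s share within groups was scaled to the gap between OVA and saline. It gave 25.9% of the OVA change (22.4 to 29.0% with each library left out, 3.28% within saline, 24.2% within OVA and 30.1% within anti-IL-4Ra). What varies within groups may thus account for part of the change of the called genes as a whole. The share was higher in every OVA than in every saline library, so the trend cannot say whether preparation accounts for most of it. With the share as a covariate the median absolute log2 change of these genes went from 0.83 (SE 0.21) to 0.54 (SE 0.26), 98.6% kept their sign and 716 of 5897 stayed called, the calls ending through both the smaller change and the larger error. A part that differs between OVA and saline without varying within groups stays open, as does an effect of OVA on the share itself.

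Goblet cell scores spread more widely among the anti-IL-4Ra libraries (3.15 to 6.23, SD 1.46) than with OVA (SD 0.87), and the lowest 2 were in replicates 5 and 2, which also had the lowest Rn45s shares of their group (1.65 and 3.10%). Taking off the ciliated cell score of each library left 74.0% of the SD (1.08), between the bounds set for either answer, so airway content and a response that varies between animals cannot be told apart with 5 libraries. A saline library under an anti-IL-4Ra label is argued against, since the lowest anti-IL-4Ra score was 2.07 above the highest saline score and the saline libraries ranged over 1.77. An OVA library under an anti-IL-4Ra label is argued against as well: on the 32 to 60 antibody genes called without the library in question, with 0 at the mean of the other OVA and 1 at that of the other anti-IL-4Ra libraries, the lowest anti-IL-4Ra library (0.685) lay 0.524 above the highest OVA library (0.160; SD 0.204 and 0.132). A difference in exposure between animals was not tested.

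Endothelial and alveolar type 1 cell markers were lower with OVA. Dilution of all resident cells by incoming cells alone is argued against, because the alveolar type 1 score minus the ciliated score fell by 1.54 (SD 0.30 with OVA and 0.51 with saline; exact permutation p = 0.00794, the smallest possible). A bias by GC content or transcript length is argued against too, as 111% of the median change of the 24 members was left after its trend over 15737 genes was removed. The Rn45s share is not excluded: its trend within groups, scaled to the gap between OVA and saline, gave 64.4% of the median change of the members (56.7 to 74.9% with each library left out; 19.6% within saline, 67.9% within OVA and 65.9% within anti-IL-4Ra), and with the share as a covariate the median went from -1.19 (SE 0.26) to -0.53 (SE 0.28), with 21 of 24 still below 0 and 1 called. RNA preparation may therefore account for most of this fall, but the share may itself follow the disease, and a larger share of airway, loss of these cells and lower expression per cell stay open, as untested.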

How the results depend on the processing

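The Rn45s and cardiac covariates, removal of Rn45s, thinning to equal depth and the fit without the libraries with the most adipose RNA were chosen only after the data were seen. Among called named genes, the antibody comparison kept its call in 536 of 582 values over all alternatives and lost it in 46, OVA against saline kept 3831 of 3944 and lost 113, and anti-IL-4Ra against saline kept 3439 of 3752 and lost 313; none changed sign. Counts that moved by over 1.5 times follow; the cause was not tested unless stated.

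For the antibody, DESeq2 called 128 genes (62 higher, 66 lower) with 99 changed back, and all 48 edgeR calls were among the 128. The stricter filter, with fewer genes tested, left 16 lower genes, and the fit of 2 groups, with fewer libraries, 13 higher. The replicate block gave 26 (11 higher, 15 lower), 24 changed back and 1346 lower genes for anti-IL-4Ra against saline, although the numbers do not pair the libraries. The threshold of 0.01, stricter by construction, gave 3433 OVA calls (1809 higher, 1624 lower), 28 antibody calls (13 and 15), 1865 for anti-IL-4Ra against saline (1084 and 781) and 25 changed back. A log2 change of at least 1 left 2261 OVA calls (1487 higher, 774 lower) and 1632 for anti-IL-4Ra against saline (1174 and 458). With the Rn45s share as a covariate there were 752 OVA calls (486 and 266) and 373 for anti-IL-4Ra against saline (322 and 51). The latter had 2780 (1446 and 1334) without saline replicate 1, OVA replicate 1 and anti-IL-4Ra replicate 4, and 1438 (878 and 560) with the cardiac covariate. With the OVA libraries split, 22.7 genes on average changed back.

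With single libraries left out, OVA calls ranged from 4776 to 6619, antibody calls from 32 to 61, anti-IL-4Ra against saline from 2844 to 4679, and genes changed back from 29 to 51. Higher antibody genes ranged from 13 (without OVA replicate 1) to 27, with 14 without anti-IL-4Ra replicate 5, and lower genes for anti-IL-4Ra against saline from 1247 (without anti-IL-4Ra replicate 3) to 2400. Under the antibody, where neither was called, Il13 was -0.31 with voom and -0.54 with the cardiac covariate, and Il5 -0.57 with that covariate and -0.086 without anti-IL-4Ra replicate 2, its values without single libraries reaching 0.52. With the replicate block, camera called type 2 cytokines for OVA (adjusted p = 0.0460) and natural killer cells for anti-IL-4Ra against saline (0.0433), and not plasma cells for the antibody (0.0703).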

Other observations

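The splits below were planned before the result was seen, while the reading of which libraries they separate and the fit with the Rn45s share were added after it.

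Of 100 splits of the 10 OVA and saline libraries, 1 gave as many calls as the real one. This was itself the real split, with 5898 calls against at most 2593 in the others, which argues against chance. The same held for anti-IL-4Ra against saline, where 1 of 100 splits, the real one, reached 4236 calls and the highest other 325. Neither result separates the treatment from the depth or the Rn45s share of the same libraries. For anti-IL-4Ra against OVA, 5 of 100 splits reached the real count of 48, with 112, 694, 1087 and 1314 calls in the others, so chance cannot be excluded for that count. Splits that call many times the real number point to a structure among these 10 libraries. All 4 put anti-IL-4Ra replicates 2 and 5 with OVA replicate 3, against anti-IL-4Ra replicates 1 and 3 with OVA replicate 2. The Rn45s share averaged 5.30% on the side of the former and 9.19% on the other in the split with 1314 calls, 3.91 and 10.6% in that with 1087, 5.29 and 9.20% in that with 694, and 6.91 and 7.57% in that with 112. With this share as a covariate the real split gave 64 calls.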
